A study of Triticum aestivum with 12 samples.

How the data were processed

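RNA of roots and flag leaves of bread wheat grown at low Fe (10 µM) or control Fe (100 µM) was sequenced, with 3 replicates in each of 4 groups. Per the labels' protocols, 1 µg of total RNA per sample went into stranded mRNA libraries with fragments near 250 bp, which were read at both ends for 101 bp. Per the submitters' processing notes, reads were checked with FastQC, trimmed with Trimmomatic 0.36, aligned with STAR 2.7.3a and tested with DESeq2 1.26.0. The genome build, the annotation and the counting program are not given in the sources used here, so how reads shared by near-identical homoeologous copies were counted is unknown, and values of single copies within a family carry that uncertainty.

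The deposited tables, 1 per tissue, hold raw read counts per gene and library, which the authors did not normalise, per the file headers of all but the root control columns. Those columns are headed without the word raw and were taken as raw counts too. Per the file headers, the log2 fold changes of low Fe over control and their standard errors come from the authors' DESeq2 fit. The score columns are, per the file headers, the Wald statistic (checked to be the fold change over its error) and the weight given to each gene by independent hypothesis weighting. The p-value columns hold the authors' Wald p-value and its weighted Benjamini-Hochberg adjusted p-value, per the file headers. Checked on the values, the tables hold only genes with an adjusted p under 0.05 and an absolute log2 fold change of at least 1, which is 2591 genes for roots and 5969 for flag leaves. Genes outside the tables are not analysed here.

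Because the tables hold part of each library, its scale could not be computed from column totals. The authors' size factors were recovered instead, from the deposited fold changes of the genes with at least 500 reads in every library (81 in roots, 114 in flag leaves). The recovered factors for low Fe replicates 1 to 3 and control replicates 1 to 3 were 1.13, 1.08, 0.710, 1.32, 1.13 and 0.773 in roots and 1.34, 1.17, 0.927, 0.910, 0.773 and 0.975 in flag leaves. DESeq2 1.42.0 with these factors gave fold changes with a median absolute difference from the authors' deposited table of 0.00196 in roots and 0.00403 in flag leaves, and 15 and 22 genes differed by over 0.1 (log2). Tested on simulated data, the recovery missed no size factor by more than 0.211% in roots and 0.101% in flag leaves. The simulated read counts were raised above those of the data, so 1289 and 1830 genes were used, against 81 and 114 here. These errors therefore do not give the accuracy reached on the data. The number of genes the authors tested was recovered from their p-values in the same way, as 81489 and 81459, of which 4434 and 10778 passed their adjusted p at any fold.

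Counts of the listed genes were fitted per tissue with edgeR 4.0.16 (quasi-likelihood, two-sided, R 4.3.3), low Fe against control, with no block and no filter on low counts. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the listed genes. Since the authors selected those genes on the same libraries, this adjustment hardly differs from none, and the count adjusted over all genes tested is given beside it. That second adjustment used the number of genes tested but could rank only the listed genes. Its counts are therefore lower bounds for the p-values of this fit. The plan for full count tables (TMM and a filter on expression) did not apply to these tables. Tested on simulated data with the tissue's own spread (biological coefficient of variation 33.97% in roots and 39.5% in flag leaves), the fit called 2-fold changes in 21% and 4% of cases and 4-fold changes in 80% and 40%, and unchanged genes in 0.167% and 0.191%. The simulation held 100 changed genes per fold among 2591 and 5969, whereas nearly all listed genes passed in the data. Its adjustment was therefore stricter, and these shares do not give the power of the fit to the listed genes. The interaction of tissue and iron had been planned only for tables of all genes. It was run on the 684 shared genes, a choice made after the tables were seen.

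The genes named were chosen by a rule fixed before the values were seen, namely the 6 largest rises and 6 largest falls per tissue at a mean of at least 20 normalised reads, and up to 2 members per gene list. The rule gave 69 genes in roots and 68 in flag leaves, of which the text names part. The 31 gene lists were fixed in advance as patterns on the annotation text, and compared with the other called genes of the table by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over both tissues (lists of fewer than 5 genes were not tested). They cover nicotianamine, deoxymugineic acid and methionine synthesis, YSL and OPT, NRAMP, ZIP, MFS and ABC transporters, iron storage, ferric reductases, heavy metal, iron-sulfur and hemerythrin proteins, bHLH, WRKY, MYB, NAC and AP2/ERF factors, jasmonate, pathogenesis-related proteins, peroxidases, glutathione S-transferases, cytochrome P450, photosynthesis, phosphate, nitrate, cell wall, senescence, grain storage, heat shock, and histones. Smaller families were counted after the data were seen. Shares that rose in roots and leaves were compared by Fisher's exact test, shared directions by an exact binomial test and subgenome shares by chi-square tests, all two-sided. The reference table held 0 identifiers of this naming and served only for the genes per subgenome. Summaries and figures used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

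Alternatives were stricter adjusted p, fold and read minimums, a replicate block, DESeq2's test, size factors or TMM computed on the listed genes, homoeologous copies collapsed, each subgenome alone, and leaving out each library in turn.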

Results

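Gene expression was measured by RNA sequencing in roots and flag leaves of bread wheat (Triticum aestivum cv. Bobwhite S26) grown in hydroponic solution with low iron or with sufficient iron. The 12 samples fell into 4 groups of 3 replicates, namely roots and flag leaves at low Fe (10 µM) and at control Fe (100 µM), all collected 8 to 10 days post anthesis, when grain filling begins. The authors' deposited tables hold raw reads per gene for the genes they called changed only, 2591 genes for roots and 5969 for flag leaves, so the column totals are not the depth of the libraries. Reads over the listed genes ranged from 412581 to 2140188 in the root libraries and from 768089 to 1481149 in the flag leaf libraries. Relative to the deepest library of each tissue, the size factors recovered from the deposited values put the shallowest root library at 53.8% and the shallowest leaf library at 57.6%. Genes are named by the identifiers and annotations of the deposited tables, and each identifier carries its chromosome (TraesCS6D02G382900 lies on 6D). The genome build and positions are not given in the sources used here. Levels are normalised reads as mean ± SD with n = 3 per group, fold changes are low Fe over control, and a fold given as a lower bound sets a group at 0 reads to 3 reads in each library, which covers counting error only.

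The first comparison asked which root genes responded to low iron. Genes for making and moving nicotianamine and mugineic acids, the metal chelators with which grasses take up iron, were among those that rose. TraesCS6D02G382900, a nicotianamine synthase, stood at 2409 ± 836 normalised reads at low Fe (n = 3) and 8.07 ± 7.62 in the control (n = 3), a 299-fold difference (log2 8.18, SE 0.85). It was 532-fold without control replicate 1 and 199-fold without control replicate 2. TraesCS5A02G552000, a second nicotianamine synthase, rose 242-fold, from 80.6 ± 61.3 to 19532 ± 8178. The aminotransferase genes TraesCS1A02G291100 and TraesCS1D02G289700, in the list for deoxymugineic acid synthesis, rose 63.2-fold and 47.2-fold. TraesCS4D02G007200, a formate dehydrogenase of the methionine salvage list, rose 4377-fold, from 2.93 ± 0.841 to 12845 ± 6395, and TraesCS7B02G130600, with the same annotation, rose 75.7-fold. By fitted fold change the largest rise was that of TraesCS1A02G265300, a wound-induced protease inhibitor, which reached 1261 ± 927 from 0, at least 429.6-fold higher. The authors' Wald test gave this gene log2 12.8 (SE 4.25) and a weighted Benjamini-Hochberg adjusted p of 0.0272. Outside these groups, the beta-galactosidase TraesCS3A02G386200 stood at 2737 ± 1368 against 0.758 ± 1.31 (3 control reads, all in replicate 1), and the F-box gene TraesCS3B02G360100 was at least 88.1-fold higher.

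Metal transporter genes were also among those that rose. The yellow stripe-like transporter 12 gene TraesCS2D02G081200, of a family that carries iron bound to chelators, reached 73.6 ± 30.1 reads from 0 in every control root, at least 25-fold higher. TraesCS7A02G327300, a putative metal transporter in the NRAMP list, was at least 99.45-fold higher (292 ± 90.0 against 0), and TraesCS7D02G324000 at least 28.09-fold higher. The zinc transporter TraesCS4A02G403300 was at least 90.56-fold higher, and TraesCS7D02G098100 rose 15.6-fold, from 352 ± 406 to 5485 ± 1590, and 46.3-fold without control replicate 1. TraesCS4B02G131400, a ZINC INDUCED FACILITATOR-LIKE 1 gene of a family that exports nicotianamine and related chelators, rose 74.2-fold (123.8-fold without control replicate 3). The vacuolar iron transporters TraesCS2B02G455300 and TraesCS2D02G432000, which move iron into the vacuole, rose 12.4-fold (18.9-fold without control replicate 1) and 12.1-fold. TraesCS1A02G374800, annotated as a zinc finger protein-like gene and placed in the list of hemerythrin and BRUTUS-type regulators, iron-binding ubiquitin ligases of the iron response, rose 29.9-fold (log2 4.90, SE 0.36), and the bHLH genes TraesCS3B02G549800 and TraesCS2B02G543800 were at least 67.9-fold and 65.88-fold higher. The Benjamini-Hochberg adjusted p of the edgeR quasi-likelihood test for the root genes named so far ran from 2.29e-05 for TraesCS4D02G007200 to 0.00209 for TraesCS7D02G098100 (n = 3 against 3).

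Among the genes that fell in roots were regulators of stress responses and genes of jasmonate synthesis. TraesCS5A02G310100, a CRT-binding factor of the AP2/ERF family, fell by 4.17 on the log2 scale (SE 0.51), from 92.3 ± 42.5 to 4.84 ± 2.12. The lipoxygenases TraesCS5A02G378700 and TraesCS5D02G388800, of the enzyme class that opens jasmonate synthesis, changed by -6.07 (SE 0.88) and -4.61 (SE 0.70) on the same scale. The first changed by -6.59 without low Fe replicate 3 and -5.49 without low Fe replicate 2, the second by -3.77 without control replicate 2. TraesCS2D02G221800, a glucan endo-1,3-beta-glucosidase, fell by 5.66 (SE 0.34), and the peroxidase TraesCS2A02G571500 changed by -4.55 (SE 0.48). The nitrate transporter 1.1 gene TraesCS1D02G214200, for nitrate uptake, fell by 2.34 (SE 0.32).

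By gene list, all 27 listed nicotianamine synthase genes rose in roots (Fisher's exact adjusted p = 1.6e-08 against the other changed root genes, Benjamini-Hochberg over the lists of both tissues). Control replicate 2 stood apart for these genes, with a median of -2.26 (log2) relative to the mean of the 3 control roots. In the methionine and S-adenosylmethionine list, which supplies the precursor of nicotianamine, 30 rose and 1 fell (Fisher's exact adjusted p = 1.6e-08). The lists of YSL and OPT transporters (35 rose, 14 fell, Fisher's exact adjusted p = 0.00136), ZIP transporters (14 and 2, 0.00222), ABC transporters (27 and 10, 0.00369), bHLH factors (26 and 6, 0.000262) and glutathione S-transferases (31 and 9, 0.000262) leaned to a rise. So did WRKY factors (15 and 5, 0.0296), NRAMP transporters (6 and 0, 0.0243, and 0.0504 without control replicate 2) and hemerythrin genes (6 and 0, 0.0243). The YSL and OPT list holds 23 genes with the OPT domain (20 rose, 3 fell), and 17 of the 18 genes named yellow stripe rose. Its other 26 genes are of the POT family, which holds nitrate and peptide transporters (15 rose, 11 fell). The AP2/ERF list (1 rose, 34 fell, Fisher's exact adjusted p = 3.2e-07) and the jasmonate list (1 and 19, 0.000567) leaned to a fall. Of the iron storage list, 5 vacuolar iron transporters rose, 3 ferritin genes and 2 desiccation-related genes fell, and the list as a whole was even (5 and 5). No lean passed the test for deoxymugineic acid synthesis (6 rose, 3 fell), MFS transporters (46 and 33, Fisher's exact adjusted p = 0.0713), the ferric reductase list (4 and 5, of which 2 and 3 are respiratory burst oxidases and only 2 are ferric reduction oxidases, both rising), heavy metal proteins (21 and 14), iron-sulfur proteins (12 and 18), MYB (10 and 14) or NAC factors (3 and 6). The same held for pathogenesis-related proteins (7 and 20), peroxidases and related enzymes (24 and 45), cytochrome P450 (35 and 55), photosynthesis (3 and 13), phosphate supply (5 and 7), nitrate and ammonium supply (6 and 14), cell wall (21 and 22), senescence (3 and 10), grain storage proteins and inhibitors (12 and 29), heat shock proteins (8 and 10) and histones and cell division (6 and 8). Several of these calls changed with the settings. The MFS list passed without low Fe replicate 1 (Fisher's exact adjusted p = 0.0244), without control replicate 2 (0.0351), at an adjusted p under 0.01 (0.0143) and with 10 reads in 3 libraries (0.0459), within a range over all alternatives of 0.0018 to 1. The NRAMP list did not pass at an adjusted p under 0.01 (Fisher's exact adjusted p = 0.0572). At an adjusted p under 0.001 the ZIP (Fisher's exact adjusted p = 0.136), ABC (0.147), hemerythrin (0.183), WRKY (0.136) and glutathione S-transferase lists (0.294) no longer passed, and the MFS (0.00666) and peroxidase lists (0.0163) did. At a log2 fold of at least 2 the ZIP (Fisher's exact adjusted p = 0.792), ABC (0.313), WRKY (0.0839) and glutathione S-transferase lists (0.0839) no longer passed. At a mean of at least 50 reads the hemerythrin (Fisher's exact adjusted p = 0.0632) and WRKY lists (0.317) no longer passed, and the MFS (0.00245), pathogenesis-related (0.0104), peroxidase (0.041) and grain storage lists (0.0175) did. Adjusted over all genes tested, the ABC (Fisher's exact adjusted p = 0.0625), hemerythrin (0.0693), WRKY (0.0625) and glutathione S-transferase lists (0.270) no longer passed, and the MFS (0.0018) and peroxidase lists (0.00323) did. By gene description text alone the MFS (Fisher's exact adjusted p = 0.0362) and grain storage lists (0.00374) passed as well. By text alone and at a log2 fold of at least 2 the NRAMP and hemerythrin lists were too short to test. So was the NRAMP list at an adjusted p under 0.001, at a mean of 50 reads and adjusted over all genes. With genes of 1 annotation on 1 chromosome group collapsed to 1 vote, the AP2/ERF (Fisher's exact adjusted p = 0.0109) and methionine lists (0.0243) passed. Nicotianamine synthase (0.123), YSL and OPT (0.634), ZIP (0.371), ABC (0.123), bHLH (0.179), WRKY (0.552), glutathione S-transferase (0.159) and jasmonate genes (0.074) did not, and the NRAMP and hemerythrin lists were too short to test. The collapse merged other copies with homoeologous ones and left few votes, 5 for the 27 nicotianamine synthase genes. Groups whose members moved in different directions gave no vote, and unplaced genes and genes without a description were left out. A lost list therefore does not single out homoeologous copies.

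Of the 2591 listed root genes, 2583 passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05 over the listed genes, of which 1180 rose and 1403 fell (45.7% rose). The genes had been selected by the authors on these libraries, so this count is not independent evidence. Adjusting for all 81489 genes the authors tested, with only the listed genes ranked, left at least 1051 genes (569 rose, 482 fell). That stricter count was 470, 330 and 1004 without low Fe replicates 1, 2 and 3, and 227, 523 and 359 without control replicates 1, 2 and 3. Size factors computed on the listed genes themselves moved root fold changes by about 0.71 (log2) and gave 1185 genes that rose and 771 that fell (60.6% rose). Under that scaling the NRAMP (Fisher's exact adjusted p = 0.184), hemerythrin (0.184), ZIP (0.0829) and WRKY lists (0.0558) no longer passed, and the MFS (0.00604) and pathogenesis-related lists (0.0241) did.

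**Figure D1:**
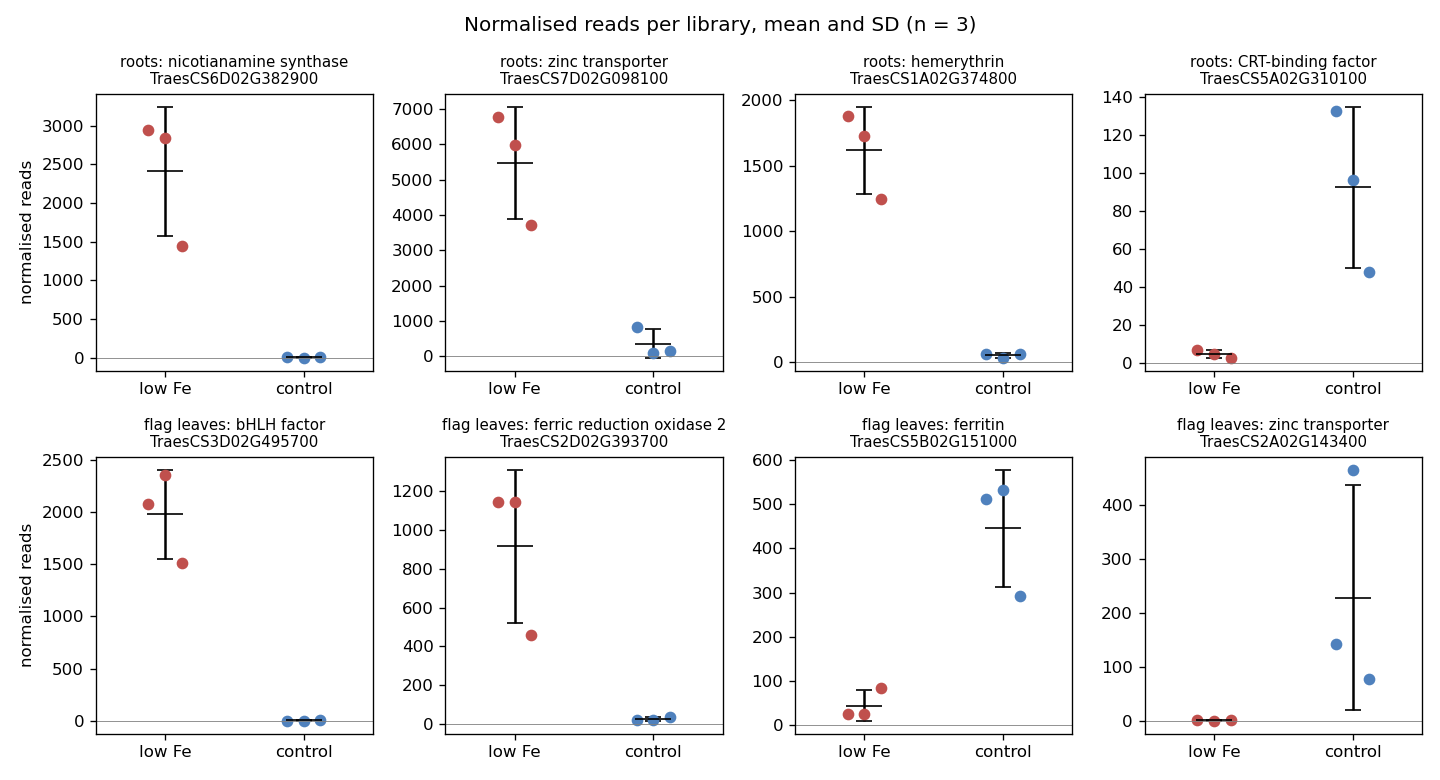
Normalised reads of 8 genes in single libraries (points), with the mean and SD of the 3 low Fe and the 3 control libraries of each tissue. In each panel the low Fe and control points lie apart; for the nicotianamine synthase TraesCS6D02G382900 in roots the means are 2409 and 8.07.

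The second comparison asked the same of flag leaves, the upper leaves that feed the filling grain. Among the genes that rose, the nicotianamine synthase TraesCS5A02G552400 reached 383 ± 290 normalised reads at low Fe (n = 3) from 0 in the control (n = 3), at least 111.96-fold higher, and the aminotransferase TraesCS1B02G300500 was at least 75.8-fold higher (46.4-fold without low Fe replicate 2). The bHLH gene TraesCS3D02G495700, of a family with known iron-deficiency regulators, rose 523-fold, from 3.78 ± 5.63 to 1980 ± 428 (log2 8.90, SE 0.82). The fold was 3604 without control replicate 3 and 349 without control replicate 2. Ferric reduction oxidase 2, which reduces ferric iron at the membrane, rose by 5.08 on the log2 scale (SE 0.50) for TraesCS2D02G393700 (916 ± 394 against 26.9 ± 10.5) and 18.5-fold for TraesCS2A02G396000. TraesCS1B02G364200, a DnaJ chaperone with a 4Fe-4S domain, rose 187-fold (283-fold without control replicate 1), and the hemerythrin gene TraesCS1A02G374800 rose 10.9-fold. The adjusted p of these genes (edgeR quasi-likelihood, Benjamini-Hochberg) lay between 0.000217 for TraesCS3D02G495700 and 0.00356 for TraesCS1B02G300500 (n = 3 against 3).

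The bHLH gene TraesCS3A02G489600 (1054 ± 408 against 0.342 ± 0.592), the Storkhead-box gene TraesCS4D02G317300 (883 ± 407 against 0.366 ± 0.635) and the B3 domain gene TraesCS4A02G241500 (873 ± 275 against 0.366 ± 0.635) also rose from almost no reads, each with 1 read in 1 control library. Among the genes that fell in flag leaves, the ferritin gene TraesCS5B02G151000, for the plastid iron store, fell by 3.33 on the log2 scale (SE 0.56). It changed by -4.17 without low Fe replicate 3. Of the 4 listed ferritin genes 3 fell and 1 rose. The zinc transporters TraesCS2A02G143400 and TraesCS7A02G420200 changed by -6.91 (SE 0.88) and -6.11 (SE 0.69), and the CDGSH iron-sulfur gene TraesCS5A02G301100 by -7.70 (SE 0.78). These were -5.87 without control replicate 2, -5.47 without low Fe replicate 1 and -8.66 without low Fe replicate 3. TraesCS2D02G134200, annotated FLOWERING LOCUS T after the mobile flowering signal, fell by 7.70 (SE 0.60), from 781 ± 246 to 3.87 ± 3.23. Without low Fe replicate 3 it changed by -8.53. The peroxidases TraesCS1B02G115900 and TraesCS6D02G054900 changed by -8.62 (SE 0.77) and -7.32 (SE 0.74). Without low Fe replicate 3 they changed by -9.73 and -8.00, and the second by -6.61 without control replicate 1. Among further genes that rose, the lipoxygenase TraesCS5D02G013400, of jasmonate synthesis, was at least 31.277-fold higher (107 ± 14.6 against 0) and the vacuolar-processing enzyme TraesCS3B02G597900, a protease of cell death, rose 38.9-fold. The SPX gene TraesCS2D02G396700, of phosphate signalling, rose 17.9-fold.

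By list, ZIP transporters fell in flag leaves (2 rose, 27 fell, Fisher's exact adjusted p = 4.3e-11), as did histones and cell division genes (11 and 32, 1.6e-08), among them all 10 histone H1 genes. WRKY factors (44 rose, 0 fell, Fisher's exact adjusted p = 3.35e-06), NAC factors (56 and 2, 6.5e-06), glutathione S-transferases (66 and 4, 1.4e-05), pathogenesis-related proteins (86 and 10, 8.6e-05) and jasmonate genes (36 and 1, 0.000354) rose more often than the other changed leaf genes, of which 70.8% rose. For pathogenesis-related genes the controls stood apart, with medians of 0.91, -1.22 and 0.31 (log2) relative to their mean against 2.44, 2.17 and 2.02 at low Fe. The highest Fisher's exact adjusted p of that list without 1 library was 0.000638. ABC transporters (72 and 10, 0.00123), cytochrome P450 (135 and 28, 0.00144) and the grain storage list (84 and 13, 0.0011) did so too, the last including lipid-transfer and cortical cell-delineating proteins rather than storage proteins alone. Iron-sulfur and ferredoxin proteins (31 rose, 35 fell, 0.000282) and MYB factors (29 and 32, 0.000699) rose less often, and all 5 ferredoxin genes fell. The iron-sulfur list did not pass under size factors (Fisher's exact adjusted p = 0.209) or TMM (0.177) computed on the listed genes, the MYB list did not under TMM (0.141), and the grain storage list under neither (0.205 and 0.052). The nicotianamine synthase list (19 rose, 3 fell, Fisher's exact adjusted p = 0.262), the methionine list (20 and 2, 0.0848), deoxymugineic acid synthesis (8 and 0, 0.203) and hemerythrin genes (6 and 0, 0.294) did not pass this test. Under size factors and TMM computed on the listed genes, the nicotianamine synthase (Fisher's exact adjusted p = 0.000886 and 0.00163), deoxymugineic acid (0.0292 and 0.0102) and YSL and OPT lists (0.0325 and 0.0428) passed, with most members higher. In the comparison as first set, on the authors' scale, no lean passed for YSL and OPT (40 and 15), NRAMP (6 and 2), MFS (84 and 30), the iron storage list (9 and 4), the ferric reductase list (15 and 9), heavy metal proteins (52 and 21), bHLH (52 and 25), AP2/ERF (16 and 12, which include peptide chain release factors), peroxidases (45 and 29), photosynthesis (52 and 33), phosphate supply (32 and 6), nitrate and ammonium supply (11 and 6), cell wall (46 and 17), senescence (47 and 23) or heat shock proteins (40 and 22). Some of these lists hold mostly other families, since their patterns also matched domain names. Of the YSL and OPT list, 18 genes have the OPT domain (16 rose, 2 fell), among them 10 named yellow stripe (9 and 1), and 37 are of the POT family (24 and 13). Of the ferric reductase list, 11 are respiratory burst oxidases, which all rose, and the other 13 mostly fell (4 and 9). Of the iron storage list, 5 are ferritin or vacuolar iron transporter genes (1 rose, 4 fell), and the 8 that are neither all rose. Within photosynthesis all 14 early light-induced proteins rose and 8 of 9 photosystem II genes fell. With copies collapsed to 1 vote per chromosome group and annotation, the ZIP (0.0233), jasmonate (0.0247) and histone lists (6.6e-06) passed, and the other 9 lists that had passed did not, with adjusted p from 0.061 for NAC to 0.61 for ABC transporters. By gene description text alone the MYB (Fisher's exact adjusted p = 0.766) and grain storage lists (0.755) no longer passed, and the peroxidase (0.00608) and photosynthesis lists (1.3e-05) did, with a smaller share that rose than the other changed genes. At a mean of at least 10 reads the photosynthesis (Fisher's exact adjusted p = 0.0398), phosphate supply (0.0377) and heat shock lists (0.0398) passed as well. At a mean of at least 50 reads the NAC (Fisher's exact adjusted p = 0.125), cytochrome P450 (0.201) and grain storage lists (0.325) no longer passed, and the AP2/ERF (0.0254), peroxidase (0.0254), photosynthesis (0.0170) and phosphate supply lists (0.000863) did. With 10 reads in 3 libraries the peroxidase (Fisher's exact adjusted p = 0.048), photosynthesis (0.0152) and phosphate supply lists (0.00768) passed. At an adjusted p under 0.01 the cytochrome P450 list was lost (Fisher's exact adjusted p = 0.0973). At 0.001 that list (Fisher's exact adjusted p = 0.346), ABC (0.217) and NAC (0.430) were lost, and 7 other lists that had passed were too short to test. At a log2 fold of at least 2 the ABC (Fisher's exact adjusted p = 0.0839), WRKY (0.0629), MYB (0.0999) and grain storage lists (0.103) were lost and the YSL and OPT list passed (0.0474). Adjusted over all genes tested, the WRKY (Fisher's exact adjusted p = 0.122), MYB (0.270) and grain storage lists (0.0642) were lost and the YSL and OPT (0.00491) and photosynthesis lists (0.00963) passed.

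Flag leaf low Fe replicate 3 stood apart. Its log2 profile correlated with replicates 1 and 2 at r = 0.863 and 0.875 across the listed genes, which are not independent replicates, against 0.963 between replicates 1 and 2. The summed nicotianamine synthase reads of all 22 listed genes were 1456 in replicate 3, lower than in each control leaf (1735 to 1994), and 6323 and 7056 in replicates 1 and 2. This sum mixes 19 genes that rose with 3 that fell. The median of the 12 nicotianamine synthase genes with a mean of at least 50 reads stood 3.43 (log2) above the control mean in replicate 3 and 7.91 and 7.97 above it in replicates 1 and 2. The corresponding medians for deoxymugineic acid synthesis were 2.76 against 5.28 and 5.30, for the methionine list 0.70 against 1.59 and 1.70, for WRKY factors 0.84 against 1.80 and 1.69, and for glutathione S-transferases 1.21 against 1.96 and 2.06. Over all listed genes that rose the medians were 1.32 against 1.93 and 1.75, and over all that fell -1.18 against -1.68 and -1.77. The ZIP list (-2.49 against -2.65 and -2.18), the senescence list (1.29 against 1.24 and 1.49) and hemerythrin genes (2.23 against 2.58 and 2.59) differed less. In roots, low Fe replicate 3 was also lower, by less, for nicotianamine synthase (6.36 against 6.99 and 6.87) and the methionine list (2.98 against 3.63 and 3.44). The same held there for deoxymugineic acid synthesis (3.14 against 4.38 and 4.46), whereas root WRKY factors were higher (2.07 against 1.78 and 1.48).

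**Figure D2:**
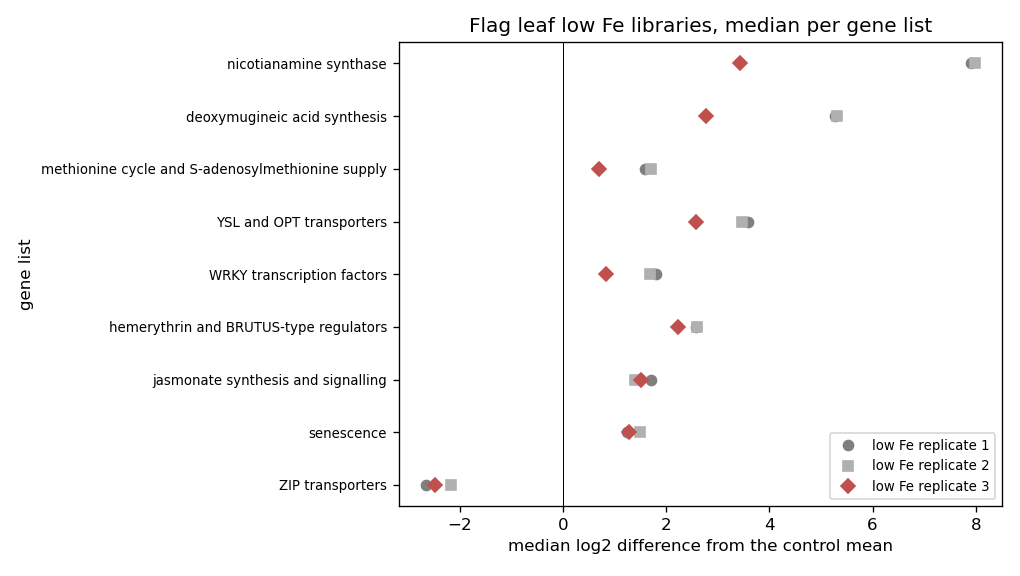
Median log2 difference from the mean of the 3 control leaf libraries, per gene list, in each low Fe leaf library, over genes with a mean of at least 50 normalised reads. For nicotianamine synthase, replicate 3 lies at 3.43 and replicates 1 and 2 at 7.91 and 7.97.

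Of the 5969 listed leaf genes, 5875 passed the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05 over the listed genes, of which 4157 rose and 1718 fell (70.8% rose). As for roots, the authors had selected these genes on the same libraries. Adjusting in the same way for all 81459 genes tested left at least 1580 (1093 rose, 487 fell). Without low Fe replicate 3 the stricter count was 3577, and it was 457 and 301 without low Fe replicates 1 and 2 and 229, 363 and 255 without control replicates 1, 2 and 3. Size factors computed on the listed genes moved leaf fold changes by -1.17 (log2) and TMM by -1.03, which gave 1174 genes that rose and 1742 that fell (40.3% rose), and 1388 that rose and 1742 that fell (44.3% rose).

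**Figure D3:**
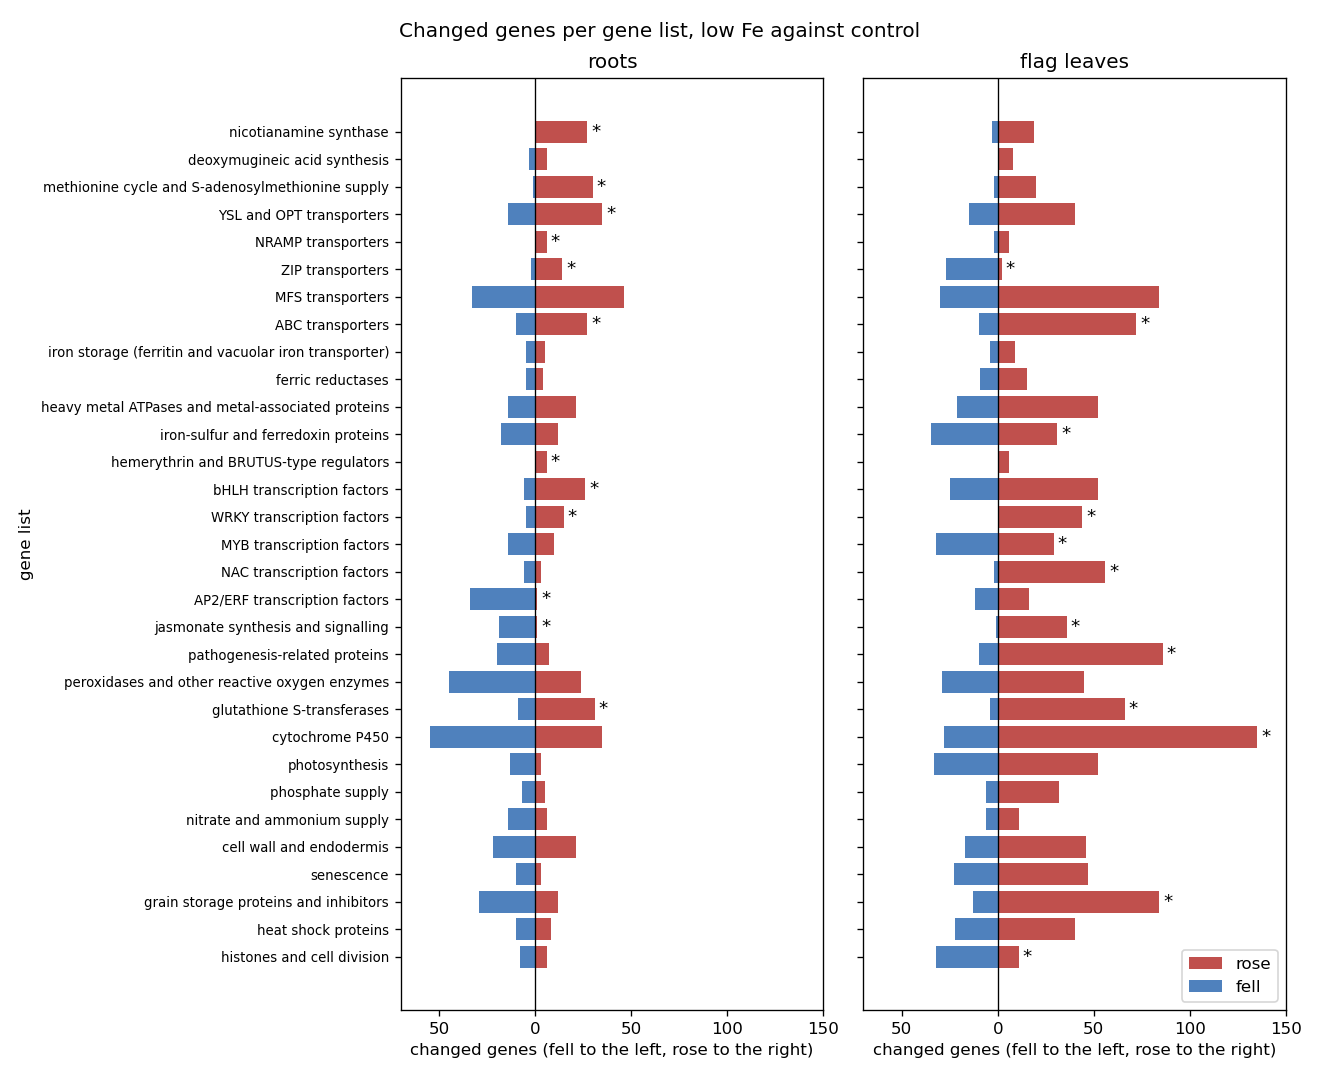
Numbers of changed genes that rose (red, to the right) and fell (blue, to the left) in each of 31 gene lists, in roots and in flag leaves; an asterisk marks a Fisher's exact adjusted p under 0.05. ZIP transporters rose in roots (14 and 2) and fell in flag leaves (2 and 27).

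The third comparison asked how far the tissues shared the response. Of the changed genes, 672 were changed in both, 340 up and 128 down in both, 183 down in roots and up in leaves and 21 the reverse. Under size factors computed on the listed genes 298 were changed in both, with 22 down in roots and up in leaves and 23 the reverse (84.9% in the same direction). Under TMM on the listed genes these were 413, with 53 and 22 (81.8%). If the same genes were tested in both tissues and each was equally likely to be called, 186 shared genes would be found. Calls need enough reads, so genes read in both tissues could overlap more than this without a shared response. The plan had kept a comparison with chance for tables of all genes tested, so the 186 decides nothing about the overlap. The direction was the same for 69.6% of the 672 shared genes against 48.2% expected (exact binomial p = 3.4e-29). Their fold changes correlated across genes at r = 0.61 (Spearman 0.55). Both tables leave out changes under 1 on the log2 scale, and genes are not independent replicates. The copper transport protein family genes TraesCS7A02G439300, TraesCS7B02G338200 and TraesCS7D02G429000 rose in roots (log2 2.19, 1.74 and 1.87) and fell in leaves (-2.75, -2.92 and -3.12). The allene oxide synthase TraesCS4B02G237600, of jasmonate synthesis, fell by 2.24 in roots and rose by 5.70 in leaves, and the repressor gene TraesCS4D02G296000, a jasmonate ZIM domain protein, changed by -1.74 in roots and rose by 2.95 in leaves. The oil-body gene TraesCS2B02G385200 (caleosin) changed by -2.58 in roots and rose by 8.06 in leaves, and the auxin efflux carrier TraesCS5A02G284500 rose by 6.11 in roots and changed by -2.72 in leaves. These 7 genes were chosen after their values were seen. An interaction of tissue and iron was fitted to the 684 genes the authors list for both tissues and passed for 324 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05; 357 at an unadjusted p under 0.05), of which 212 moved in opposite directions and 112 the same way by different amounts. The authors had selected genes changed by at least 1 (log2) in each tissue, so genes of opposite sign differ by at least 2 through the selection, and all 212 passed. Under size factors and TMM computed on the listed genes, fitted after the data were seen, the interaction passed for 376 and 359 genes, of which 204 and 280 were among the 324. By the directions of each scaling, 153 of the 376 moved in opposite directions and 223 the same way. Of the 359 these were 202 and 157. Ferric reduction oxidase 2 rose more in leaves than in roots, by 3.36 (log2, SE 0.53) for TraesCS2D02G393700. This was 1.398 under size factors and 2.23 under TMM computed on the listed genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0258 and 0.00429). For the other copy, TraesCS2A02G396000, the difference was 2.83 on the authors' scale, and it did not pass under size factors computed on the listed genes.

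**Figure D4:**
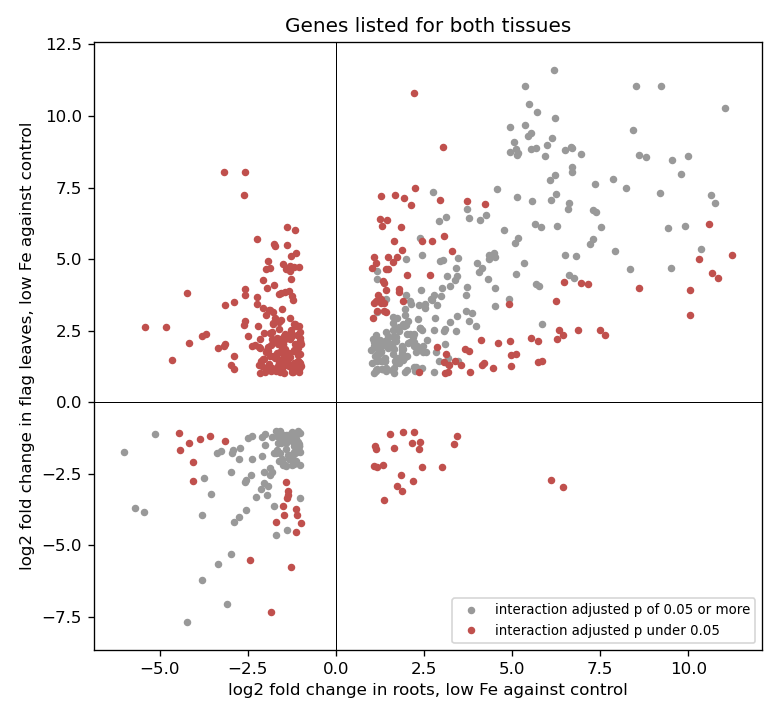
Log2 fold change in flag leaves against that in roots for the 684 genes listed for both tissues; red points passed the interaction test. The 212 genes with opposite signs lie in the upper left and lower right.

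Of the changed genes, 45.7% rose in roots and 70.8% in leaves, a difference of 25.1 percentage points (Fisher's exact p = 2.9e-105, odds ratio 2.88). At an adjusted p under 0.001 the difference was 9.33 points (60.8% rose in roots, 70.1% in leaves). It was 19.6 points at a log2 fold of at least 2 (56.9 and 76.5%) and 15.0 adjusted over all genes tested (54.1 and 69.2%). At these stricter settings most root genes rose. Under size factors computed on the listed genes the difference was -20.3 points and under TMM on the listed genes -1.43 (Fisher's exact p = 0.285). Both scalings are set on the changed genes alone, so they do not decide what this difference rests on. Under size factors and TMM the share that rose was 40.3 and 44.3% in leaves and 60.6 and 45.8% in roots. Over the lists, 14 of 31 differed between the tissues in the share that rose (Fisher's exact, Benjamini-Hochberg), a test that does not remove the difference over all changed genes. Under size factors and under TMM computed on the listed genes 8 of 30 lists differed each, and ZIP transporters, jasmonate genes and pathogenesis-related proteins did so on all 3 scales. Under size factors these were the only 3 of the 14, and the other 5 lists (MFS, heavy metal, iron-sulfur, bHLH and histones) rose less often in leaves. Under TMM 7 of the 14 differed, and histones besides. On the authors' scale the lists with the smallest adjusted p were jasmonate genes (1 rose and 19 fell in roots, 36 and 1 in leaves, Fisher's exact adjusted p = 1.9e-11), cytochrome P450 (3.0e-11, lost under size factors with a difference of 0.490 points), grain storage (8.2e-10), pathogenesis-related proteins (2.0e-09), ZIP transporters (4.7e-07) and AP2/ERF factors (5.5e-06).

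Changed genes were spread over the A, B and D subgenomes at 34.04, 32.6 and 33.3% in roots, with no difference past the threshold from the 32.5, 34.5 and 33.1% of protein-coding genes in the reference (chi-square p = 0.108). In flag leaves they were 32.0, 32.6 and 35.3%, with more genes from the D subgenome than the reference share (chi-square p = 0.000617). The D subgenome's excess was not past the threshold with the 395 genes at an adjusted p under 0.001 (chi-square p = 0.479) or with adjustment over all genes tested (0.111).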

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

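The tests of explanations in this part, including the splits, were chosen only after the results were seen, apart from the time-of-day test, whose genes and prediction were written before its value was seen.

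The tissues differed in the share of changed genes that rose, by 25.1 percentage points, and 324 shared genes passed the interaction test. Of 100 splits drawn within the tissues, 1 (the real split) gave as many, with a highest other of 258. The genes had been selected on the real groups, which favours the real split, so this count of splits does not decide about chance. For the counts within a tissue, 1 of the 10 splits reached the real value (2583 in roots with a highest other of 1, 5875 in flag leaves with a highest other of 48), and 10 splits are too few for a share under 0.05.

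By gene list, the share that rose differed between leaves and roots (Fisher's exact test) by 92.3 points for jasmonate genes, 63.7 for pathogenesis-related proteins, 63.2 for NAC factors, 57.3 for grain storage, 54.3 for AP2/ERF and -80.6 for ZIP transporters. Smaller differences were 44.1 points for senescence, 43.9 for cytochrome P450, 42.5 for phosphate supply, 42.4 for photosynthesis, 26.0 for peroxidases, 25 for WRKY factors, 24.2 for cell wall and 16.8 for glutathione S-transferases, beside 25.1 for all changed genes. The difference passed under size factors and TMM computed on the listed genes as well for ZIP transporters, jasmonate genes and pathogenesis-related proteins, and for the other 11 lists it was lost under at least 1 of them. Under size factors 5 lists outside the 14 differed, all lower in leaves, namely histones (-48.7 points), heavy metal proteins (-38.6), iron-sulfur proteins (-34.6), bHLH factors (-32.9) and MFS transporters (-31.5).

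Among the named genes, the log2 fold change in leaves minus that in roots passed the interaction test at 8.57 for TraesCS4D02G317300, 6.36 for TraesCS5A02G143200, 5.88 for TraesCS3D02G495700, 5.25 for TraesCS1B02G364200, 4.75 for TraesCS1B02G061800, 3.36 for TraesCS2D02G393700, 2.83 for TraesCS2A02G396000, 2.7004 for TraesCS1D02G352600 and 1.31 for TraesCS6B02G265800. It was negative for TraesCS3B02G549800 (-6.17), TraesCS7A02G327300 (-6.07), TraesCS5B02G397600 (-3.02), TraesCS7B02G130600 (-2.696), TraesCS3B02G414900 (-2.30) and TraesCS1A02G374800 (-1.46). Where a group had 0 reads, as for TraesCS3B02G549800 and TraesCS7A02G327300 in control roots, the fitted value depends on the prior count. Under size factors computed on the listed genes, a fit added after the data were seen, TraesCS6B02G265800 turned to -0.51 and did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.480; 0.26 under TMM, 0.691). TraesCS1D02G352600 (0.84, 0.284), TraesCS2A02G396000 (0.93, 0.103) and TraesCS1B02G061800 (2.88, 0.105) were lost under size factors and passed under TMM, and the other 11 passed under both.

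Nicotianamine synthase genes were lower in flag leaf low Fe replicate 3 than in replicates 1 and 2. Control leaf RNA mixed in at one fraction would lower all genes nearly silent in the control alike, yet the median level was 6.93% of replicates 1 and 2 for 11 nicotianamine synthase genes and 35.8% for 212 other such genes (quartiles 15.7 and 59.2, permutation p = 0.017), and the summed reads (1456) lay under those of every control leaf (1735 to 1994), lower than any mixture of control leaves with replicates 1 and 2. Both argue against it, although homoeologous copies are not independent and the list was picked because it stood out. Lower depth of the library was already divided out by the size factors, so it was not tested as such. Any factor left over for the whole library would move all genes alike. The median was 9.25% of replicates 1 and 2 for 12 nicotianamine synthase genes and 86.9% for 2428 other listed genes (quartiles 56.9 and 140.1). These values argue against such a factor, although the list was picked because it stood out. Another time of day stays open: the clock genes' difference lay at percentile 62.7 of matched lists, but 5 of the 19 genes matched were jasmonate ZIM-domain genes, so the test decides little. Root low Fe replicate 3 was also lower for nicotianamine synthase genes, by less, with a median of 6.36 (log2) above the control mean against 6.99 and 6.87. No biological explanation was tested, since the design names no group that sets replicate 3 apart.

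Jasmonate genes fell in roots and rose in flag leaves. Scaling of the libraries is argued against, since the highest Fisher's exact p under the other scalings was 2.9e-06. A single library is argued against too, with a highest Fisher's exact p of 4.6e-12 over the fits without each library. The genes had been selected on all libraries and copies of a gene are not independent, which makes these p-values smaller than they should be. With copies collapsed, the jasmonate list passed in flag leaves (16 rose, 0 fell, Fisher's exact adjusted p = 0.0247). Groups whose copies disagreed gave no vote there, so a fall within such a group is not counted. In roots the collapsed jasmonate list did not pass (0 and 8, 0.074). Handling or wounding at harvest that differed between the tissues was not tested and stays open, as does a difference between the tissues themselves.

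Most changed genes rose in flag leaves. Few reads in many of the genes may add to this, since the difference from roots was 14.4 points at a mean of at least 50 normalised reads against 25.1 over all changed genes, but it is argued against as the whole cause (Fisher's exact p = 1.1e-18). Scaling cannot be told apart from a real asymmetry: a shift of 1.38 (log2) would even the listed genes that rose and fell, and the genes outside the tables, which would show such a shift, are not analysed here.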

How the results depend on the processing

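The stricter adjusted p, fold and read minimums, the block, DESeq2's test, size factors on the listed genes, collapsed copies and leaving out libraries were chosen before the data were examined; TMM on the listed genes, 10 reads in 3 libraries, adjustment over all genes tested, the authors' calls, description text alone, the interaction, and the lists between tissues, description groups and interaction under other scalings were chosen after seeing the data. Of 231 values for the main results, 203 stayed. For counts and correlations this meant lying within a set ratio or distance of the main value. For tests it meant keeping the direction and side of the threshold. Another 24 values were counts that moved further. The share that rose, leaves minus roots, reversed to -20.3 points under size factors computed on the listed genes and was lost under TMM on them, at -1.43 points (Fisher's exact p = 0.285). Both scalings are set on the changed genes alone. The difference shrank to 9.33 points at an adjusted p under 0.001 and 15.0 adjusted over all genes tested, where most root genes rose (60.8 and 54.1%). The interaction value of TraesCS6B02G265800 reversed to -0.51 under those size factors. By construction fewer genes pass stricter settings. Roots gave 750 genes at an adjusted p under 0.001, 1096 at a log2 fold of at least 2, 1463 at a mean of at least 50 reads and 1051 adjusted over all genes tested. Flag leaves gave 3462 genes at an adjusted p under 0.01, 395 at 0.001, 2827 at a log2 fold of at least 2, 2430 at 50 reads, 2916 with size factors and 3130 with TMM on the listed genes, and 1580 adjusted over all genes tested. Genes changed in both tissues numbered 417 and 74 at the stricter adjusted p, 232 at the fold minimum, 244 at 50 reads, 298 with size factors, 413 with TMM, 174 adjusted over all genes, and 225, 225 and 212 in the A, B and D subgenomes alone. Gene lists that passed numbered 24, against 10 at an adjusted p under 0.001, 15 at the fold minimum and 5 with copies collapsed. The leaf D share was 35.7% at an adjusted p under 0.001 (chi-square p = 0.479) and 35.2% adjusted over all genes (0.111), where fewer genes were tested. The cause of the other changes was not tested. The planned pseudocounts do not apply to counts and were not run.

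Leaving out 1 library gave 2491 to 2565 genes in roots, 4656 to 5842 in flag leaves, 573 to 670 in both, 69.4 to 71.7% with the same direction, r from 0.59 to 0.64, 306 to 360 interactions, 24 to 25 lists, a rising-share difference of 24.2 to 26.8 points, and D shares of 33.3 to 33.6% in roots and 35.2 to 35.5% in leaves. Adjusted over all genes tested, roots gave 227 to 1004 genes and flag leaves 229 to 3577, lower bounds that are given per library in the account of each tissue. Of 1242 values for gene lists, 1146 stayed, 59 were lost and 37 gained. Of 2545 values for named genes, 2479 stayed and 66 were lost, 42 of them at an adjusted p under 0.001 and 15 adjusted over all genes. The replicate block gave 2586 genes in roots, 5865 in flag leaves and 318 interactions; samples of 1 number correlated at 0.05, 0.01 and 0.06 in roots and 0.15, 0.05 and 0.07 in leaves across genes (0.196, 0.101 and 0.105 at a mean of at least 50 reads, and not all over 0.1 in roots), and each low Fe leaf library correlated best with its own number, a hint from the data and not the design. In the simulation with 3 replicates and this spread, most 2-fold changes were not called. It held a far smaller share of changed genes than the data, so its adjustment was stricter.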

Other observations

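The test of different ZIP members was planned before its value was seen, whereas the descriptions were tested only after the data were seen, 112 of them, of which 33 passed (Fisher's exact, Benjamini-Hochberg).

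In roots, aquaporins, which are water channels, fell (1 rose, 26 fell, Fisher's exact adjusted p = 5.1e-05), as did glycosyltransferases (4 and 28, 0.00141) and WAT1-related proteins (1 and 12, 0.023). Laccases, of lignin synthesis, rose (13 and 3, 0.023), and so did DETOXIFICATION efflux carriers (9 and 1, 0.03002). Metallothioneins (10 rose, 2 fell) and germin-like proteins (10 and 1) were counted without a test. Under size factors computed on the listed genes the laccases (Fisher's exact adjusted p = 0.0564) and DETOXIFICATION carriers (0.238) no longer passed and the WAT1-related proteins were too few to test, while all 5 groups passed under TMM.

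In flag leaves, the phenylalanine ammonia-lyases, which open phenylpropanoid synthesis, rose (21 and 0, Fisher's exact adjusted p = 0.00687), with the FtsH metalloproteases (22 and 0, 0.00521) and the serine/threonine kinases (71 and 4, 2.1e-05). SWEET sugar transporters fell (4 rose, 15 fell, 0.000184), as did bZIP factors (0 and 11, 4.9e-05), amino acid permeases (5 and 12, 0.00436) and serine-rich proteins (0 and 12, 2.1e-05), the last from 1 chromosome group. Alternative oxidases (8 rose, 1 fell, with 3 in the iron storage list), respiratory burst oxidases (11 and 0, also part of the ferric reductase list) and Hsp20 chaperones (20 and 5) were counted without a test. Under size factors and TMM computed on the listed genes the SWEET transporters no longer passed (Fisher's exact adjusted p = 0.160 and 0.0610), the kinases were lost under size factors (0.0598), and the phenylalanine ammonia-lyases were too few to test under size factors and lost under TMM (0.0610). The other 4 groups passed under both.

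Different members of the ZIP family may respond in each tissue. Of the 16 ZIP genes listed for roots and 29 for flag leaves, 4 were in both tables, which is 25% of the root genes and meets the bound set in advance exactly, so the test leaves it undecided. Of those 4, TraesCS7A02G361000 (log2 1.15 in roots, -2.28 in leaves) and TraesCS7D02G362100 (1.32 and -2.20) moved in opposite directions.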
